A study of Mus musculus with 18 samples.

How the data were processed

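RNA of lymphatic endothelial cells (LEC) and blood vascular endothelial cells (BEC) from mouse embryos was hybridised to 18 Affymetrix Mouse Gene 1.0 ST arrays, a platform with probes along the exons of each gene. Per the labels, the samples fall into 6 groups, LEC and BEC at embryonic days 14.5, 16.5 and 18.5, each with 3 biological replicates from independent litters. Per the design text, matching LEC and BEC samples of 3 litters were compared at each age. The main fit did not pair them. How the cells were separated is given in the labels only by a citation to another publication, which was not used here.

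The deposited values are log2 expression values, which the authors made with oligo 1.54.1 and RMA, per the submitters' processing notes. RMA is a method that corrects background, quantile-normalizes the arrays and summarises the probes of each transcript cluster. Whether all 18 arrays were normalized together, the summary level and any filter are not given in the sources used here. The interquartile range of the values per array was 3.182 to 3.641 and the median 5.434 to 5.582, so the arrays did not share 1 distribution over all transcript clusters. Arrays give no read depth, and the number of arrays limits the precision.

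The table held 35556 transcript clusters. The platform annotation listed 23410 of them, of which 21789 had exactly 1 gene symbol and 1621 had several, and 12146 were not listed and are unnamed here. Entrez identifiers of 21698 single-symbol clusters were found in the reference gene table, and 0 symbols changed through them. Clusters with several or no symbols were not tested. For the 999 genes with more than 1 cluster, the cluster with the highest mean over all arrays was used, which left 19938 genes, with no filter on dim genes. Among genes named in the text, another cluster of the gene pointed the other way at an unadjusted p under 0.05 for Hk1 (change with age in LEC) and Top2a (difference of the age changes). Values of near-identical families, such as histone genes, the Mrgpr receptors, embryonic globins and small RNA genes, are uncertain because probes of 1 member may bind another.

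Group means were fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes without trend), with 12 residual degrees of freedom and 6.11 prior degrees of freedom. There were 7 contrasts: LEC minus BEC as the mean of the 3 ages and at each age, E18.5 minus E14.5 in LEC and in BEC, and the difference between these age changes (LEC minus BEC), which is the interaction test. P values are from limma, two-sided and adjusted by Benjamini-Hochberg over the 19938 genes within a contrast, and a gene was called at an adjusted p under 0.05. Differences are on the log2 scale, so that 1 is a 2-fold difference, and errors are limma standard errors (SE).

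Before the data were examined, 29 gene lists were fixed, 18 of endothelial identities and programs and 11 of other cell types that an endothelial isolate might hold. They name 378 genes, of which 356 were measured and 22 had no single-symbol cluster. The endothelial lists are lymphatic endothelial identity, blood endothelial identity, pan-endothelial, arterial, venous, tip cell and sprouting, lymphatic valve, VEGFC, adrenomedullin and angiopoietin signalling, haematopoietic and haemogenic regulators, Notch pathway, cell cycle, basement membrane, endothelial transport and lipid handling, leukocyte adhesion and trafficking, interferon response and antigen presentation, immediate early and dissociation response, glycolysis, and fatty acid oxidation. The other lists are markers of macrophages, lymphocytes and leukocytes, mast cells, erythroid cells, platelets and megakaryocytes, keratinocytes and epithelium, fibroblasts, mural cells, neurons and Schwann cells, skeletal muscle, and hepatocytes. Each list was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. The same test with an estimated correlation, and fry, which asks whether a list's genes move on balance one way, were run beside it. Members were counted as past the threshold over all genes and again adjusted over the list alone. Of the camera calls, 14 of 19 held with an estimated correlation for LEC against BEC over the 3 ages, 11 of 18 at E14.5, 13 of 19 at E16.5 and 9 of 18 at E18.5. For the age changes, 0 of 11 held in LEC and 5 of 15 in BEC, and 5 of 14 held for the difference between them.

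Named genes were chosen by a rule fixed before the data were examined, which passed over predicted genes, RIKEN clones, and olfactory, vomeronasal and microRNA genes. It took the 12 largest differences each way between LEC and BEC among genes whose arrays did not overlap at any age, and the 3 largest each way at each age among genes called at that age only whose groups did not overlap there. For the age changes it took the 10 largest rises and falls per cell type whose groups did not overlap, and the 6 largest each way for the difference of the age changes. With 3 arrays against 3, chance alone separates the groups of 10% of genes. From a described list up to 4 members with the smallest p were named, and Prox1 and the GATA factors were always reported. The contrasts, tests, alternatives and lists were likewise fixed before the data were examined.

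The procedure was tested on simulated data, with 200 of 19938 genes changed by 0.5, 1 or 2 on the log2 scale. At a difference of 1, it recovered 100.0% of changed genes for LEC against BEC over the 3 ages, 97.0% at E14.5, 88.1% at E16.5 and 88.1% at E18.5. It recovered 94.0% for the age change in LEC, 91.0% in BEC and 61.2% for the difference of the age changes. At a difference of 0.5 these shares were 80.6%, 43.3%, 31.3%, 37.3%, 35.8%, 34.3% and 6.0%, in the same order. False calls made up 4.6%, 1.9%, 6.4%, 6.2%, 7.3%, 2.0% and 5.9% of the calls, so 4 of the 7 contrasts exceeded 5%, with 7 to 12 false calls each. Camera called 20 of 20 lists shifted by 1 and 2 of 560 unshifted lists. The simulated genes varied independently of each other and with the same spread in every group. The simulation therefore says nothing about false calls for lists whose genes vary together. It also changed fewer genes (200) than any contrast of the data called (1765 to 8149). The adjustment of p depends on the share of changed genes, so the shares recovered may differ in the data.

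The alternatives were the replicate number within each age as a fixed or random block, an intensity trend with robust variances, array weights, only the compared groups in the fit, no variance moderation, repeated quantile normalization, a shift to a common median, filters on dim genes, other ways to collapse or keep clusters, stricter thresholds, and each array left out in turn. A fit without the E18.5 arrays was added after the data were seen.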

Results

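Gene expression was compared between LEC, which line lymphatic vessels, and BEC, which line blood vessels, in mouse embryos at E14.5, E16.5 and E18.5, with 3 arrays in each of the 6 groups. The title of the series places the data in a study of how LEC identity is controlled through an enhancer that the transcription factor GATA2 binds. Arrays of 1 group correlated at 0.976 to 0.992 with the other arrays of that group. The leading principal component held 47.7% of the variance and separated LEC arrays (25.7 to 47.5) from BEC arrays (-47.3 to -29.6). The next held 26.4% and set the E18.5 arrays (31.5 to 46.9) apart from the earlier ages (-38.4 to -7.75). The 6 arrays of E18.5 had a narrower spread of values than the 12 earlier arrays, with a mean interquartile range of 3.293 against 3.539 (exact two-sided permutation p = 5.4e-05). The permutation treated arrays as independent, although LEC and BEC samples of an age come from matching litters, so this p may be too small. The narrower spread goes with every change from E14.5 to E18.5 described here.

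The regulators the series is about were both higher in LEC. Prox1, the homeodomain factor that specifies lymphatic fate, was higher in LEC by 4.20 ± 0.09 (SE) over the 3 ages (limma adjusted p = 2.7e-17). At the single ages it was higher by 2.51 ± 0.15 at E14.5, 4.99 ± 0.15 at E16.5 and 5.09 ± 0.15 at E18.5. Gata2 was higher in LEC by 1.99 ± 0.12 (adjusted p = 5.1e-11), and by 1.73 ± 0.21, 2.33 ± 0.21 and 1.92 ± 0.21 at the same ages. For both genes the 3 LEC arrays lay above the 3 BEC arrays at each age. From E14.5 to E18.5, Prox1 rose by 0.65 ± 0.15 in LEC and fell by 1.94 ± 0.15 in BEC, and these changes differed (2.58 ± 0.22, adjusted p = 4.1e-07). Gata2 fell by 1.03 ± 0.21 in LEC and fell by 1.22 ± 0.21 in BEC, and the difference of 0.19 ± 0.29 between these changes was not past the test (adjusted p = 0.79). Without the E18.5 arrays, a fit chosen after seeing the data, the difference of Gata2 from E14.5 to E16.5 was 0.28 in LEC (adjusted p = 0.2) and -0.32 in BEC (adjusted p = 0.13), so that in LEC its mean level was lower at E18.5 only.

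Among the other GATA factors, Gata1, a regulator of erythroid, megakaryocyte and mast cells, was higher in LEC by 1.52 ± 0.10 (adjusted p = 2.5e-10). It fell with age by 1.24 ± 0.17 in LEC and by 0.95 ± 0.17 in BEC. Without the E18.5 arrays its differences from E14.5 to E16.5 were -0.03 in LEC (adjusted p = 0.94) and -0.50 in BEC (adjusted p = 0.074). Gata3 did not differ over the 3 ages (0.07 ± 0.10, adjusted p = 0.64), though without the E18.5 arrays the difference was -0.38 (adjusted p = 0.02). It was lower in LEC at E14.5 (-0.72 ± 0.18, adjusted p = 0.0068) and higher at E18.5 (0.98 ± 0.18, adjusted p = 0.00027). With age it differed by 1.69 ± 0.18 in LEC against 0.00 ± 0.18 in BEC (difference 1.70 ± 0.25, adjusted p = 0.0002). That rise too lay after E16.5, since from E14.5 to E16.5 the difference was -0.06 in LEC (adjusted p = 0.85) and -0.74 in BEC (adjusted p = 0.0092), and 0.68 between them (adjusted p = 0.13). Gata6 rose with age by 1.82 ± 0.17 in LEC and 1.43 ± 0.17 in BEC. Its lower level in LEC (-0.29 ± 0.10, adjusted p = 0.024) was no longer past the test without BEC E14.5 replicate 2 (-0.25), BEC E18.5 replicate 2 (-0.24), LEC E14.5 replicate 3 (-0.27) or LEC E16.5 replicate 1 (-0.25). Gata4 (-0.02 ± 0.09) and Gata5 (-0.14 ± 0.10) did not differ past the test (adjusted p = 0.9 and 0.28).

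**Figure D1:**
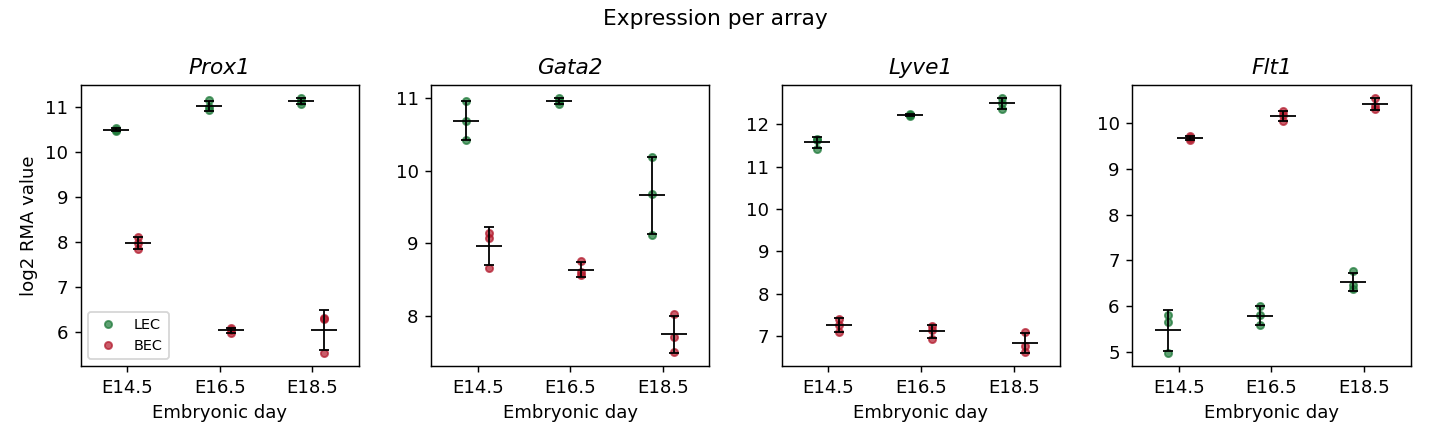
Expression (log2, RMA) of Prox1, Gata2, Lyve1 and Flt1 in LEC and BEC at E14.5, E16.5 and E18.5; points are arrays and bars the mean ± SD of 3 arrays. Prox1 in BEC lies at 7.84 to 8.10 at E14.5 and at 5.52 to 6.31 at E18.5, while Gata2 in LEC lies at 10.43 to 10.96 and at 9.12 to 10.19.

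LEC and BEC were then compared over the 3 ages, which asks what distinguishes the vessel types throughout this part of development. All 15 measured genes of the lymphatic identity list were higher in LEC (median 2.32, camera adjusted p = 3.6e-22). Among them were the hyaluronan receptor Lyve1 (5.03 ± 0.07, adjusted p = 6.5e-19), the secreted glycoprotein Reln (4.68 ± 0.08) and the guidance factor Sema3d (4.46 ± 0.11). Of 16 genes of blood endothelial identity, 15 were lower in LEC (median -2.95, camera adjusted p = 1.5e-18), among them the VEGF receptor Flt1 (-4.14 ± 0.10), Notch4 (-3.06 ± 0.07) and Cd93 (-2.83 ± 0.07). Other large differences toward LEC were those of Fgl2 (4.74 ± 0.09), the sodium channel Scn3a (4.25 ± 0.08), Tc2n (4.25 ± 0.13), the pentraxin Ptx3 (4.13 ± 0.14), Mmrn1 (4.03 ± 0.10) and the polarity gene Pard6g (3.79 ± 0.07). Toward BEC they were those of Asb4 (-4.83 ± 0.16), Tmem255a (-4.79 ± 0.18), the apelin receptor Aplnr (-4.65 ± 0.18), the water channel Aqp1 (-4.58 ± 0.17) and the junction proteins Esam (-4.37 ± 0.12) and Jam2 (-4.02 ± 0.11). The transcription factor Mecom (-4.32 ± 0.14), Palmd (-4.10 ± 0.14), Lpar4 (-4.08 ± 0.13), Sparcl1 (-3.97 ± 0.13) and C1qtnf9 (-3.87 ± 0.08) were lower in LEC as well.

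The pan-endothelial list and lists of vessel programs were on balance lower in LEC. Some hold members of the blood identity list, such as Notch4, Nrp1 and Sox17 in the arterial and Esm1 and Apln in the tip cell list, and in part repeat its result. Of 16 pan-endothelial genes, 11 were lower and 1 higher (median -0.82, camera adjusted p = 1.1e-08), with Clec14a at -3.68 ± 0.12 and Robo4 at -2.52 ± 0.08. In the arterial list 12 of 16 were lower (median -1.30, adjusted p = 1.2e-09), such as Nrp1 (-3.74 ± 0.12) and Sox17 (-2.45 ± 0.09). In the tip cell list 9 were lower and 3 higher (median -1.51, adjusted p = 4.1e-05), such as Mcam (-3.48 ± 0.07) and Igfbp3 (-3.49 ± 0.08). Basement membrane genes were lower for 11 of 14 (median -1.11, adjusted p = 4.7e-11), with the collagen genes Col15a1 at -3.66 ± 0.07 and Col4a1 at -2.03 ± 0.06. Of 16 genes of endothelial transport and lipid handling, 11 were lower and 5 higher (median -1.38, adjusted p = 3.8e-05), the fatty acid carriers Cd36 (-3.12 ± 0.09) and Fabp4 (-2.82 ± 0.09) among the lower ones. Notch pathway genes were lower for 11 of 16 and higher for 2 (median -0.63, adjusted p = 2.2e-05), Mfng at -2.70 ± 0.08 and Notch2 opposite at 2.51 ± 0.07. Leukocyte adhesion genes were lower for 9 of 14 and higher for 2 (median -0.56, adjusted p = 0.0004), with the E-selectin gene Sele at -2.84 ± 0.16 and Madcam1 at -2.85 ± 0.09.

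In the lymphatic valve list 10 of 18 genes were higher and 4 lower in LEC (median 0.70, camera adjusted p = 0.0023; adjusted p = 0.16 with an estimated correlation). The semaphorin Sema3a lay at 3.49 ± 0.06, the valve regulator Foxc2 at 2.88 ± 0.10 and, opposite to them, the connexin gene Gja5 at -3.52 ± 0.14. Of 19 haematopoietic and haemogenic regulators, 11 were higher and 1 lower (median 0.27, adjusted p = 7.1e-06), Myb at 2.41 ± 0.11, Ikzf1 at 2.38 ± 0.10 and Runx1 at 1.42 ± 0.07. Venous genes were lower for 5 of 9 and higher for 2 (median -0.60, adjusted p = 0.046; adjusted p = 0.24 with an estimated correlation), Vwf at -3.33 ± 0.10 and Nrp2 opposite at 0.88 ± 0.06. The venous call was lost with the replicate block (adjusted p = 0.055), with a common median (adjusted p = 0.078) and with any of 4 single arrays left out. Cell cycle genes were lower for 7 of 22 by small amounts (median -0.10, adjusted p = 0.03; adjusted p = 0.44 with an estimated correlation), Cdk1 by -0.68 ± 0.06. Without the E18.5 arrays the venous (adjusted p = 0.084) and cell cycle calls (adjusted p = 0.49) were lost. Not past camera were VEGFC, adrenomedullin and angiopoietin signalling (5 higher and 4 lower of 16, median 0.08, adjusted p = 0.47), interferon response (3 higher and 8 lower of 14, -0.23, adjusted p = 0.17) and immediate early genes (6 higher and 3 lower of 14, 0.10, adjusted p = 0.63). Nor were glycolysis (4 higher and 4 lower of 13, 0.06, adjusted p = 0.79) and fatty acid oxidation (3 higher and 6 lower of 15, -0.06, adjusted p = 0.66). Within the VEGFC list, the receptor Flt4 was higher (2.03 ± 0.07) and its ligand Vegfc lower (-2.06 ± 0.07) in LEC. The mean (-0.01) of the glycolysis list had the opposite sign to its median and test.

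Markers of other cell types differed between the isolates as well. All 16 macrophage genes were higher in LEC (median 2.43, camera adjusted p = 4.1e-15), with the mannose receptor Mrc1 at 4.50 ± 0.13, F13a1 at 3.90 ± 0.19 and Fcgr3 at 2.92 ± 0.12. All 9 mast cell genes were higher too (median 2.68, adjusted p = 5.6e-09), with Ms4a2 at 3.37 ± 0.15 and the tryptase gene Tpsb2 at 2.86 ± 0.21. Leukocyte genes were higher for 9 of 11 and lower for 1 (median 1.62, adjusted p = 2.7e-08), Ptprc at 2.93 ± 0.13. These lists moved with the higher Gata2, Gata1 and other haematopoietic regulators of the LEC arrays. Keratinocyte and epithelial genes were higher for 12 of 14 and lower for 1 (median 0.85, adjusted p = 5.7e-05; adjusted p = 0.23 with an estimated correlation), Epcam at 0.83 ± 0.09. Mural cell genes were lower for 11 of 12 (median -0.94, adjusted p = 5.5e-08), Rgs5 at -2.66 ± 0.13 and Notch3 at -1.24 ± 0.07, beside the lower basement membrane and Notch genes. Erythroid genes were lower for 5 of 8 (median -0.27, adjusted p = 0.046; adjusted p = 0.16 with an estimated correlation), Alas2 at -1.89 ± 0.11. The erythroid call was lost with a common median (adjusted p = 0.071) and with any of 3 single arrays left out.

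Platelet (1 higher and 4 lower of 6, adjusted p = 0.28) and fibroblast genes (1 higher and 5 lower of 14, adjusted p = 0.1) were not past camera. Neither were neuron and Schwann cell (1 higher of 10, adjusted p = 0.79), skeletal muscle (4 lower of 11, adjusted p = 0.48) and hepatocyte genes (1 lower of 8, adjusted p = 0.79). For platelets the median was -0.41 and the mean 0.00, and for neurons and Schwann cells the median of -0.02 opposed the mean of 0.03 and the test. Adjusted over the list alone, the counts of members differed from those over all genes as follows. There 12 pan-endothelial, 10 tip cell, 7 valve, 6 VEGFC, 12 Notch, 10 leukocyte adhesion and 0 hepatocyte genes were lower. In the other direction, 12 haematopoietic, 4 fatty acid oxidation and 1 erythroid genes were higher.

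Over the 3 ages 7404 of 19938 genes differed, 3624 higher and 3780 lower in LEC, and 1266 of them by at least 1 (739 and 527). With the arrays shifted to a common median the split was 3036 higher and 5012 lower, so the share of higher calls moved from 48.9% to 37.7%, and the balance between the directions depends on the scaling.

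The comparison at each age asks which of these differences were present early or appeared late. At E14.5, 3297 genes differed (1714 higher and 1583 lower in LEC), 5032 at E16.5 (2593 and 2439) and 6071 at E18.5 (2908 and 3163). The order of the ages depends on the fit, and the cause was not tested. With only the compared groups in the fit the counts were 4160, 5116 and 3707, and with array weights 4895, 6125 and 4240, so that E18.5 had the lowest count. Arrays correlated less within groups at E18.5 (0.976 to 0.978 in LEC, 0.977 to 0.982 in BEC) than at E14.5 (0.991 to 0.992 and 0.988 to 0.991). The main fit pools the spread of all groups, so it may understate the error at E18.5. By at least 1, 989, 1538 and 1565 genes differed at the 3 ages. At all 3 ages 1163 genes were higher and 1121 lower in LEC, 26 were called at all 3 in different directions, and 301, 964 and 2293 were called at E14.5, E16.5 or E18.5 only. The median lymphatic identity gene was higher in LEC by 1.5 at E14.5, 2.79 at E16.5 and 2.79 at E18.5 (15 of 15 genes at each age, and 15 adjusted over the list alone). The median blood identity gene lay at -2.93, -3.19 and -2.90. Valve genes were not past camera at E14.5 (9 higher and 5 lower of 18, median 0.25, adjusted p = 0.093). They were past it at E16.5 (11 and 4, 0.80, adjusted p = 0.00077; adjusted p = 0.11 with an estimated correlation) and E18.5 (11 and 2, 0.94, adjusted p = 4.1e-06), where Foxc2 reached 3.75 ± 0.17. Adjusted over the list alone, 5 valve genes were lower at E16.5 and 3 at E18.5.

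At E14.5 only, Angpt1, a ligand of the Tek receptor, was higher in LEC by 1.84 ± 0.27 (adjusted p = 3.5e-05), Plac8 by 1.68 ± 0.22 and the melanocortin receptor Mc5r by 1.18 ± 0.19. The YAP target genes Ccn2 (-1.32 ± 0.12) and Ankrd1 (-1.02 ± 0.18), and Tecrl (-1.05 ± 0.22), were lower there. Called at E16.5 only were the keratin Krt4 (1.30 ± 0.18), Mlph (1.27 ± 0.18) and Ephx4 (1.27 ± 0.18) on the LEC side. On the BEC side were the glutamate receptor Gria2 (-1.26 ± 0.18), the small RNA genes Snora69 (-1.02 ± 0.21) and Rny1 (-1.35 ± 0.38, adjusted p = 0.013). The Rny1 call was lost without BEC E16.5 replicate 2 (-1.04, adjusted p = 0.084) and without moderation of the variance (adjusted p = 0.051). At E18.5 only, the desmosomal cadherin Dsc3 (2.81 ± 0.31), Clec12b (2.28 ± 0.24) and Ctsj (2.27 ± 0.18) were higher, and Car3 (-2.70 ± 0.52), the chemokine Cxcl10 (-2.55 ± 0.26) and the angiotensin receptor Agtr1a (-2.40 ± 0.22) lower. Tecrl (at most 4.31) and Rny1 (at most 4.73) lay below 4.78, a bound for dim genes, on all 18 arrays. For Angpt1, Plac8, Mc5r, Ankrd1, Krt4, Ephx4, Snora69 and Ctsj the lower group lay below it at the age named. The sizes of these differences are therefore uncertain. Interferon response genes were lower for 9 of 14 and higher for 2 at E18.5 (median -0.78, camera adjusted p = 0.0019; adjusted p = 0.19 with an estimated correlation). Cell cycle genes were lower for 13 of 22 and higher for 1 there (15 lower adjusted over the list alone; median -0.31, adjusted p = 0.00025; adjusted p = 0.19 with an estimated correlation).

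Macrophage genes were higher in LEC for 9 of 16 at E14.5 (10 adjusted over the list alone; median 0.95, camera adjusted p = 3.3e-07; adjusted p = 0.094 with an estimated correlation). They were higher for 16 at E16.5 (median 2.81, adjusted p = 2.2e-16) and for 15 at E18.5 (median 3.17, adjusted p = 1.6e-17). All 9 mast cell genes were higher at each age, with medians of 1.87, 2.27 and 3.71 (adjusted p = 0.075, 0.066 and 0.054 with an estimated correlation). Mural cell genes were lower for 5 of 12 and higher for 1 at E14.5 (median -0.28; adjusted p = 0.12 with an estimated correlation), a call lost with a common median (adjusted p = 0.051) and with any of 3 single arrays left out. They were lower for 8 at E16.5 (-0.69) and for 11 at E18.5 (-1.85, camera adjusted p = 5.3e-11), with 6 and 9 lower at the earlier ages adjusted over the list alone. A shift to a common median moved the median difference of all genes at E16.5 from -0.002 to -0.109 and the split from 2593 higher and 2439 lower (51.5% higher) to 1987 and 3602 (35.6%).

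**Figure D2:**
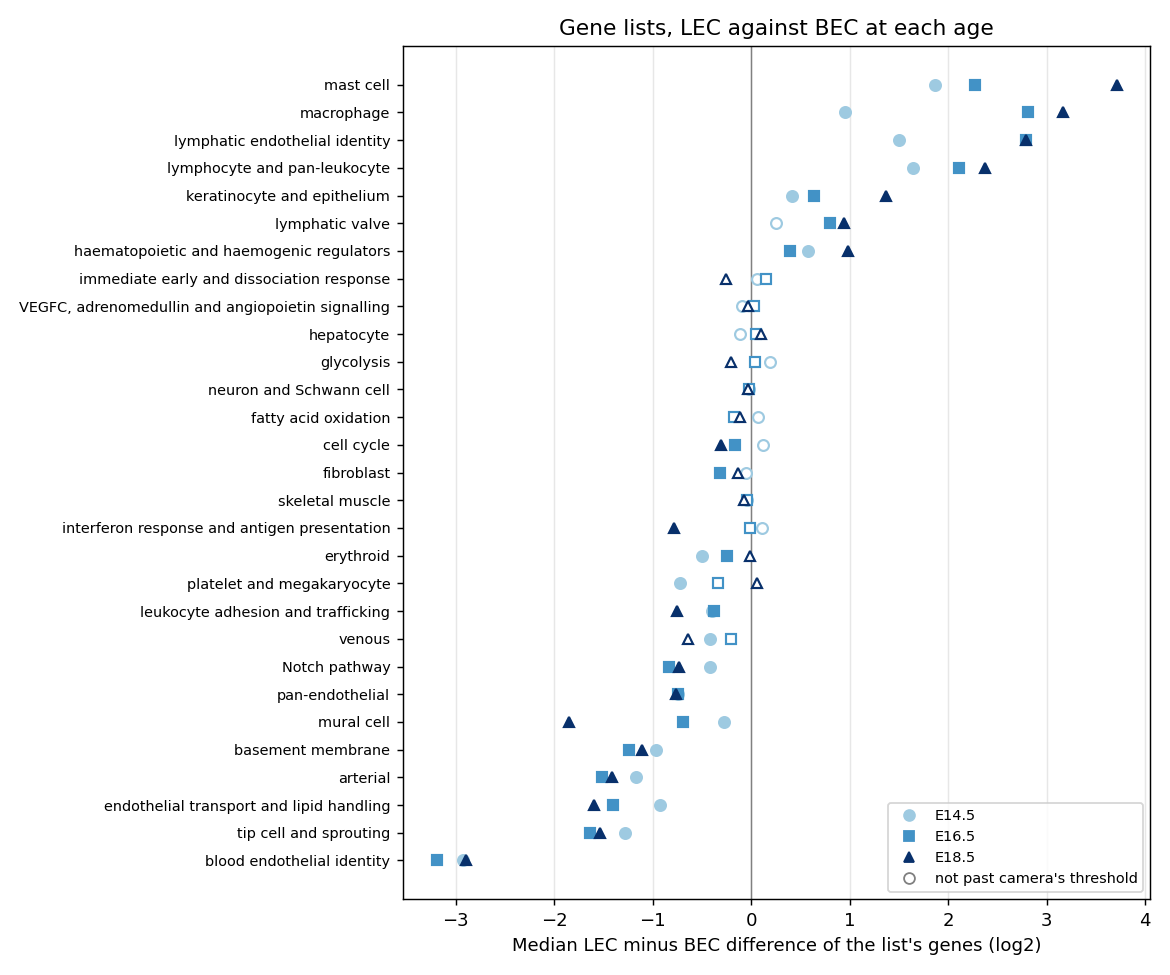
Median LEC minus BEC difference (log2) of each gene list at E14.5, E16.5 and E18.5; marks are medians over the measured genes of a list. The macrophage list lies at 0.95, 2.81 and 3.17, and the mural cell list at -0.28, -0.69 and -1.85.

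**Figure D3:**
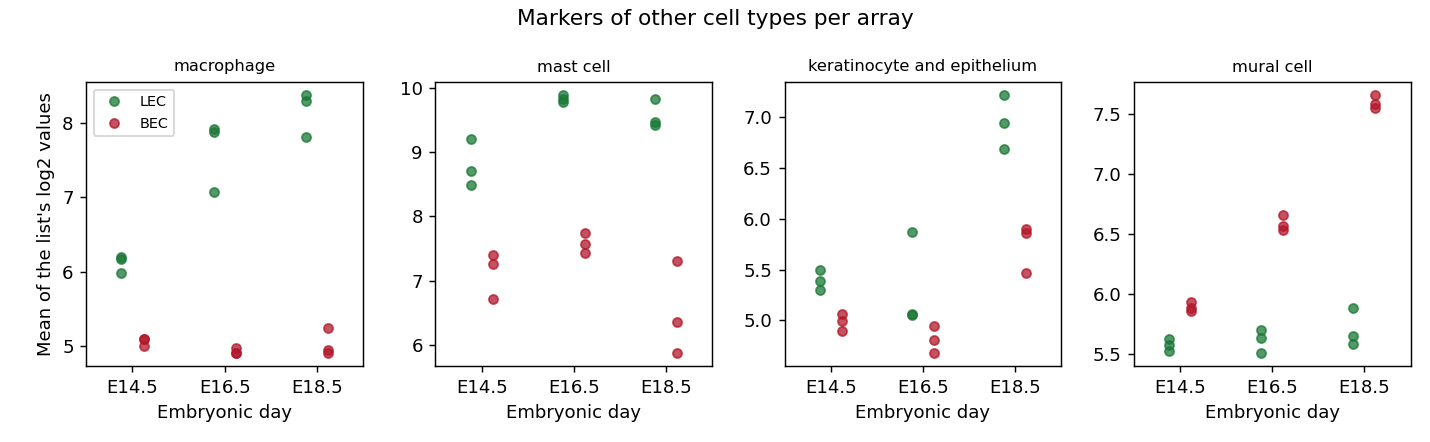
Mean log2 expression of the macrophage, mast cell, keratinocyte and mural cell lists by embryonic day; each point is 1 array of LEC or BEC. The macrophage mean in LEC lies at 5.976 to 6.195 at E14.5 and 7.806 to 8.370 at E18.5, and the mural cell mean in BEC at 5.858 to 5.931 and 7.549 to 7.658.

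The change within LEC from E14.5 to E18.5 asks how lymphatic endothelium matures. Cell cycle genes fell for 20 of 22 (median -1.04, camera adjusted p = 5.7e-13; adjusted p = 0.067 with an estimated correlation). Among them were the replication licensing genes Mcm5 (-1.55 ± 0.10) and Mcm2 (-1.44 ± 0.10) and the nucleotide reductase subunit Rrm2 (-1.43 ± 0.09). Glycolysis genes fell for 10 of 13 and rose for 1 (median -0.70, adjusted p = 2.3e-05; adjusted p = 0.24 with an estimated correlation), Pgam1 by -1.58 ± 0.12 and Tpi1 by -1.19 ± 0.11. Lymphatic valve genes rose for 12 of 18 and fell for 2 (median 1.05, adjusted p = 6.1e-06; adjusted p = 0.13 with an estimated correlation). Examples are the ephrin Efnb2 (1.93 ± 0.10), Sema3a (1.76 ± 0.11), the connexin gene Gja4 (2.06 ± 0.15) and Fn1 (1.15 ± 0.09). Lymphatic identity genes rose for 8 of 15 and fell for 2 but were not past camera as a list (median 0.46, adjusted p = 0.17). Lyve1 rose by 0.93 ± 0.13, Ackr2 by 1.34 ± 0.19 and Tbx1 changed by -0.63 ± 0.09.

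Immediate early genes rose for 9 of 14 and fell for 1 (median 0.97, camera adjusted p = 0.00013), with Fos at 1.88 ± 0.13 and Jun at 1.66 ± 0.10. Interferon response genes rose for 7 of 14 and fell for 1 (0.62, adjusted p = 0.012), Ifit3 by 2.10 ± 0.24. With an estimated correlation these gave adjusted p = 0.34 and 0.4. The venous list rose for 6 of 9 genes (0.58, adjusted p = 0.0072), and the leukocyte adhesion list rose for 9 of 14 and fell for 1 (0.57, adjusted p = 0.0025). Transport and lipid handling rose for 9 of 16 and fell for 4 (0.46, adjusted p = 0.031), and the arterial list rose for 8 of 16 and fell for 3 (0.34, adjusted p = 0.038). In this order the 4 lists gave adjusted p = 0.24, 0.067, 0.4 and 0.4 with an estimated correlation. Among their members were Tek (1.68 ± 0.10), Jam2 (1.73 ± 0.19), Fabp4 (2.38 ± 0.15) and Bmx (1.64 ± 0.14).

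Macrophage genes rose in LEC for 14 of 16 and fell for 1 (median 1.93, camera adjusted p = 5.2e-07; adjusted p = 0.24 with an estimated correlation). The scavenger receptor Cd163 rose by 5.47 ± 0.28 and F13a1 by 4.94 ± 0.33, both among the 10 largest rises. Others of those rises were Mrgprb2, a receptor of connective tissue mast cells (5.80 ± 0.32), and its relatives Mrgprb1 (7.04 ± 0.39) and Mrgprx2 (5.69 ± 0.34). So were Klrb1f (5.42 ± 0.20), Ms4a4a (5.39 ± 0.30), Pkhd1l1 (4.99 ± 0.18), the substance P precursor Tac1 (4.91 ± 0.39) and ceruloplasmin, Cp (4.88 ± 0.19). In LEC at E14.5 Mrgprb1 (3.25 to 3.35), Mrgprb2 (2.46 to 3.53) and Mrgprx2 (2.08 to 2.41) lay below 4.78, a bound for dim genes. Cd163 (3.74 to 3.86), Pkhd1l1 (3.31 to 4.03) and Tac1 (2.64 to 3.21) did so as well. The sizes of the rises of these genes, and their order, are therefore uncertain. The mast cell list itself rose for 3 of 9 genes and was not past camera (median 0.46, adjusted p = 0.17), though it was without LEC E14.5 replicate 2 (adjusted p = 0.042; adjusted p = 0.56 with an estimated correlation). By steps chosen after seeing the data, it rose from E14.5 to E16.5 (median 0.88, adjusted p = 7.7e-05; adjusted p = 0.27 with an estimated correlation). From E16.5 to E18.5, 3 of its genes fell and 1 rose (-0.49, adjusted p = 0.45). Keratinocyte genes rose for 11 of 14 (median 1.74, adjusted p = 1.8e-06; adjusted p = 0.29 with an estimated correlation), Epcam by 2.39 ± 0.16. Their median step was 0.02 to E16.5 (adjusted p = 0.71) and 1.83 after it (adjusted p = 4.6e-09; adjusted p = 0.24 with an estimated correlation). The largest falls were those of the embryonic globin Hbb-y (-5.22 ± 0.27), Nnat (-3.17 ± 0.15), Il3 (-3.05 ± 0.34), the mast cell and basophil protease Prss34 (-3.01 ± 0.19) and the 5S RNA gene n-R5s136 (-3.0 ± 0.49). The intermediate filament Nes (-2.93 ± 0.16), Ephx2 (-2.80 ± 0.15), the serine synthesis enzyme Phgdh (-2.74 ± 0.18), the histone gene H4c6 (-2.70 ± 0.12) and Nkg7 (-2.64 ± 0.20) fell next. In LEC at E18.5 Hbb-y (3.47 to 4.49) and Ephx2 (4.05 to 4.39) lay below 4.78, so the sizes of their falls are uncertain.

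In LEC 8149 genes changed, 3930 rising and 4219 falling, 1571 of them by at least 1 (802 and 769), and 3978 differed between E14.5 and E16.5 in the fit without the E18.5 arrays (2195 and 1783). The balance depends on the genes kept: 2548 rose and 3972 fell (39.1% rising) with the dimmer 50% of genes left out, and 6309 and 5787 over all transcript clusters (52.2%). In the fit without the E18.5 arrays Il3 (0.96, adjusted p = 0.097), Prss34 (-0.35, adjusted p = 0.12), n-R5s136 (-1.04, adjusted p = 0.16) and Nkg7 (-0.05, adjusted p = 0.86) were not past the test. Of the lists past camera, the arterial (adjusted p = 0.087) and keratinocyte lists (adjusted p = 0.7, with a downward test) were not past it there, and the arterial call was also lost with either of 2 single arrays left out. Newly past it at the preset correlation only were lymphatic identity, pan-endothelial, tip cell, haematopoietic, fatty acid oxidation and mast cell genes, rising, and erythroid genes, falling. With an estimated correlation they gave adjusted p = 0.35, 0.33, 0.33, 0.39, 0.33, 0.23 and 0.16 in this order. Adjusted over the list alone, 13 valve genes rose and 11 glycolysis genes fell, and the other counts given for LEC were the same. The fibroblast (median -0.05, mean 0.17) and neuron lists (-0.07 and 0.42), not past camera, had medians opposite in sign to their means and tests.

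In the BEC arrays lymphatic transcripts fell over the same interval. RNA of LEC in the isolates of E14.5 cannot be told apart from expression in BEC as their source. Of 15 lymphatic identity genes, 13 fell (median -1.11, camera adjusted p = 7.1e-11; adjusted p = 0.0089 with an estimated correlation). Among them were Mmrn1 (-2.70 ± 0.17), Reln (-2.34 ± 0.15), the VEGFC receptor Flt4 (-1.62 ± 0.11) and Tbx1 (-1.45 ± 0.09). Mural cell genes rose for 11 of 12 (median 1.09, adjusted p = 1.6e-10; adjusted p = 0.0014 with an estimated correlation). Rgs5 rose by 4.19 ± 0.22, the smooth muscle actin gene Acta2 by 3.93 ± 0.25, Pdgfrb by 2.22 ± 0.13 and Notch3 by 2.05 ± 0.12. Interferon response and antigen presentation genes rose for 11 of 14 (median 1.12, adjusted p = 7.3e-10; adjusted p = 0.032 with an estimated correlation), Ifit1 by 3.61 ± 0.30, Irf1 by 2.12 ± 0.13 and Tap1 by 1.88 ± 0.17. Leukocyte adhesion genes rose for 8 of 14 and fell for 1 (median 0.71, adjusted p = 5e-05; adjusted p = 0.0089 with an estimated correlation), Sele by 5.47 ± 0.28 and Jam2 by 2.51 ± 0.19.

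Immediate early genes rose for 12 of 14 in BEC (median 1.21, camera adjusted p = 1.6e-10; adjusted p = 0.06 with an estimated correlation), Fosb by 2.25 ± 0.13 and Fos by 1.96 ± 0.13. Cell cycle genes fell for 16 of 22 (median -0.61, adjusted p = 2.3e-08; adjusted p = 0.085 with an estimated correlation), Mcm5 by -1.10 ± 0.10. Glycolysis genes fell for 7 of 13 and rose for 2 (-0.39, adjusted p = 0.008; adjusted p = 0.35 with an estimated correlation), Pgam1 by -0.97 ± 0.12. Venous (5 of 9 rose, median 0.78, adjusted p = 0.002), arterial (8 rose and 2 fell of 16, 0.44, adjusted p = 0.0075) and transport genes (8 rose and 3 fell of 16, 0.28, adjusted p = 0.0054) rose on balance. The lists gave adjusted p = 0.11, 0.22 and 0.25 with an estimated correlation. Examples are Vwf (1.84 ± 0.18), Jag1 (1.67 ± 0.12) and Fabp4 (2.56 ± 0.15). Haematopoietic regulators fell for 9 of 19 and rose for 1 (median -0.39, adjusted p = 0.019; adjusted p = 0.35 with an estimated correlation), Ikzf1 by -1.35 ± 0.17. Beside them leukocyte genes fell for 5 of 11 and rose for 1 (-0.56, adjusted p = 0.016; adjusted p = 0.35 with an estimated correlation), Coro1a by -2.21 ± 0.15. Mast cell genes fell for 5 of 9 and rose for 1 beside the fall of Gata2, Cma1 by -1.80 ± 0.34, Tpsb2 by -1.35 ± 0.36 and Cpa3 by -1.51 ± 0.47, but the list was not past camera (median -0.79, adjusted p = 0.088). That call turns on single arrays: it was past camera without BEC E14.5 replicate 3 (adjusted p = 0.022; adjusted p = 0.49 with an estimated correlation) and without BEC E18.5 replicate 1 (adjusted p = 0.0019; adjusted p = 0.31 with an estimated correlation). From E16.5 to E18.5 the list fell (-1.02, adjusted p = 0.0023; adjusted p = 0.38 with an estimated correlation). Platelet genes fell for 5 of 6 (-0.72, adjusted p = 0.0027; adjusted p = 0.032 with an estimated correlation). Keratinocyte genes rose for 8 of 14 (0.74, adjusted p = 0.002; adjusted p = 0.4 with an estimated correlation), and fibroblast genes rose for 7 of 14 and fell for 2 (0.31, adjusted p = 0.046; adjusted p = 0.53 with an estimated correlation).

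Other large rises in BEC were those of the interferon-induced GTPase Iigp1 (5.14 ± 0.28), Cxcl10 (4.39 ± 0.26), the cytokine Il6 (4.19 ± 0.36), Car3 (3.71 ± 0.52), Ifi203 (3.64 ± 0.28) and the matrix protein Fbln2 (3.47 ± 0.20). In BEC at E14.5 Iigp1 (3.04 to 3.52), Car3 (4.03 to 4.42) and Ifit1 (3.50 to 3.92) lay below 4.78. The sizes of the rises of these genes, and their order, are therefore uncertain. Other large falls were those of Hbb-y (-6.24 ± 0.27), Ptx3 (-3.57 ± 0.24), Crmp1 (-2.75 ± 0.12), Igfbp2 (-2.59 ± 0.13), Hapln1 (-2.36 ± 0.27), Rgs18 (-2.35 ± 0.30), the chemokine receptor Ccr8 (-2.33 ± 0.24) and Prss34 (-2.29 ± 0.19). Hbb-y (3.11 to 4.28), Ptx3 (3.57 to 4.62) and Ccr8 (3.60 to 3.92) lay below 4.78 at E18.5, so the sizes of their falls are uncertain. In BEC 6092 genes changed, 2644 rising and 3448 falling (43.4% rising), 931 of them by at least 1 (485 and 446), and 2083 and 3583 with the dimmer 50% of genes left out (36.8%). Without the E18.5 arrays 3318 differed between E14.5 and E16.5 (1641 and 1677). There Il6 (0.44, adjusted p = 0.34), Car3 (0.32, adjusted p = 0.73), Ifit1 (0.00, adjusted p = 0.99), Rgs18 (-0.13, adjusted p = 0.76) and Ccr8 (-0.09, adjusted p = 0.83) were not past the test. Nor were the haematopoietic (adjusted p = 0.12), cell cycle (adjusted p = 0.14), leukocyte (adjusted p = 0.35) and keratinocyte lists (adjusted p = 0.24, with a downward test) past camera there. Newly past it at the preset correlation only were blood identity, pan-endothelial, basement membrane, fatty acid oxidation and mast cell genes, rising, and erythroid and muscle genes, falling. With an estimated correlation they gave adjusted p = 0.13, 0.21, 0.48, 0.064, 0.42, 0.13 and 0.063 in this order. In the fit to all arrays the step from E14.5 to E16.5 was not past camera for the basement membrane and mast cell lists (adjusted p = 0.055 for both). For the muscle list that step, downward, was past camera at the preset (adjusted p = 0.0049) and the estimated correlation (adjusted p = 0.031). With single arrays left out, the haematopoietic call was lost for 2 arrays and the fibroblast call for 3.

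The macrophage list, not past camera in BEC (2 rose and 4 fell of 16, adjusted p = 0.85), had a median of 0.21 against a mean of -0.03 and a downward test. The tip cell list (2 rose and 5 fell of 16, adjusted p = 1) had a median of 0.07 against a mean of -0.05. The valve list (7 rose and 5 fell of 18, adjusted p = 0.85) had a median of -0.05 against a mean of 0.08. Adjusted over the list alone, 9 arterial genes, 9 keratinocyte genes and 2 haematopoietic regulators rose and 9 glycolysis, 6 leukocyte, 6 mast cell and 5 macrophage genes fell, and the other counts given for BEC were the same. Rises were shared by 1651 genes and falls by 2721 between the cell types, against 521 and 730 for independent lists of these sizes, and 139 genes changed in opposite directions. Across genes, which are not independent replicates, the changes correlated at r = 0.68.

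**Figure D4:**
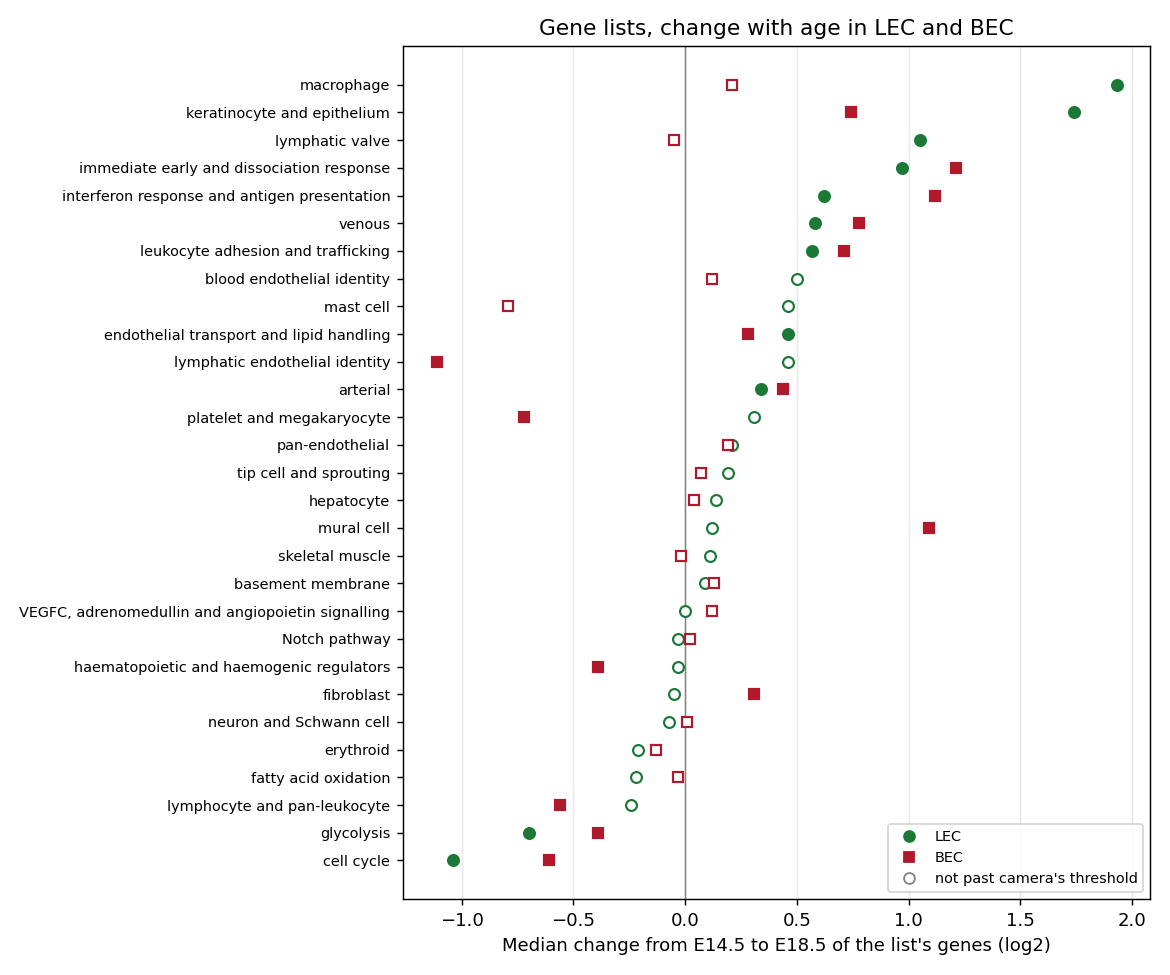
Median change (log2) of each gene list from E14.5 to E18.5 in LEC (circles) and BEC (squares); filled marks passed camera and open marks did not. The lymphatic identity list lies at 0.46 in LEC and -1.11 in BEC, the mural cell list at 0.12 and 1.09, and the cell cycle list at -1.04 and -0.61.

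The interaction test asks which changes differed between the cell types. Lymphatic identity genes changed more positively in LEC for 13 of 15 (median difference 1.53, camera adjusted p = 2.3e-21), Mmrn1 by 3.68 ± 0.24, Reln by 2.89 ± 0.21 and Sema3d by 2.87 ± 0.26. So did valve genes for 6 of 18 (0.31, adjusted p = 1.1e-09), Gja4 by 2.60 ± 0.21, Sema3a by 2.35 ± 0.15 and Fn1 by 1.92 ± 0.13. Mural cell genes changed more positively in BEC for 10 of 12 (-1.57, adjusted p = 6.3e-15), with Pdgfrb at -3.73 ± 0.19 and Rgs5 at -2.79 ± 0.31. The macrophage list differed toward LEC for 12 of 16 (2.25, adjusted p = 2.2e-16), with Cd163 at 4.95 ± 0.40 and Mrc1 at 2.96 ± 0.33, and so did the platelet list for 3 of 6 (0.76, adjusted p = 2.8e-06), with Pf4 at 4.52 ± 0.40. These 5 lists held with an estimated correlation.

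A further 9 lists were past camera only at the preset correlation. Toward LEC these were the mast cell list (4 of 9 genes, median 1.66; adjusted p = 0.22 with an estimated correlation) and keratinocyte genes (6 of 14, 0.81; adjusted p = 0.26 with an estimated correlation). Haematopoietic regulators did so as well (3 of 19 and 1 the other way, 0.22; adjusted p = 0.36 with an estimated correlation). Toward BEC were the cell cycle (11 of 22, -0.47; adjusted p = 0.078 with an estimated correlation), interferon response (5 of 14 and 2 the other way, -0.64; adjusted p = 0.2 with an estimated correlation) and glycolysis (5 of 13, -0.39; adjusted p = 0.2 with an estimated correlation). So were the Notch pathway (2 of 16 and 1 the other way, -0.32; adjusted p = 0.13 with an estimated correlation), immediate early genes (2 of 14, -0.12; adjusted p = 0.53 with an estimated correlation) and fibroblast genes (4 of 14 and 1 the other way, -0.19; adjusted p = 0.51 with an estimated correlation). Among their members, Psmb8 and Tap1 of antigen presentation differed by -2.08 ± 0.18 and -1.65 ± 0.24, Rrm2 by -0.84 ± 0.13 and Epcam by 1.60 ± 0.22. With the replicate block the Notch (adjusted p = 0.094) and immediate early calls (adjusted p = 0.054) were lost. The haematopoietic, immediate early and fibroblast calls were lost with fry (adjusted p = 0.064, 0.12 and 0.11). Leaving out single arrays ended the Notch call for 9 arrays, the fibroblast call for 7, the immediate early call for 6 and the haematopoietic call for 4. Without the E18.5 arrays the interferon (adjusted p = 0.95), immediate early (adjusted p = 0.89), glycolysis (adjusted p = 0.89) and keratinocyte lists (adjusted p = 0.65) were not past camera, the interferon and immediate early lists with an upward test, and the arterial list was (adjusted p = 0.01; adjusted p = 0.26 with an estimated correlation), toward BEC.

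The largest single differences toward LEC were those of Mrgprb1 (5.27 ± 0.55), Mrgprb2 (5.08 ± 0.45), Cd163, Mrgprx2 (4.88 ± 0.48), Klrb1f (4.82 ± 0.29) and Pkhd1l1 (4.67 ± 0.25). Toward BEC they were those of Il6 (-4.44 ± 0.50), Pdgfrb, Galnt15 (-3.04 ± 0.22), Rgs5, Sele (-2.75 ± 0.39) and the lipase Mgll (-2.75 ± 0.24). In BEC Mrgprb2 (2.93 to 4.73), Mrgprx2 (2.46 to 4.65) and Pkhd1l1 (3.55 to 4.05) lay below 4.78 at both E14.5 and E18.5. Mrgprb1 (3.37 to 3.73), Cd163 (3.75 to 4.17) and Klrb1f (3.82 to 4.17) lay below it in BEC at E14.5. The sizes of the differences toward LEC of these genes, and their order, are therefore uncertain. The changes differed for 1765 genes, 1001 toward LEC and 764 toward BEC (56.7% toward LEC), 666 of them by at least 1. The balance depends on the genes kept, with 445 and 221 (66.8%) by at least 1 and 871 and 868 (50.1%) with the dimmer 50% of genes left out. There were 923 at an adjusted p under 0.01 and 839 between E14.5 and E16.5 without the E18.5 arrays, where Il6 stood at 0.58 (adjusted p = 0.55). Adjusted over the list alone, 7 valve, 14 macrophage, 6 mast cell, 7 keratinocyte and 4 haematopoietic genes differed toward LEC and 15 cell cycle, 7 interferon, 8 glycolysis, 3 Notch and 4 immediate early genes toward BEC. Median and mean differed in sign for the arterial (-0.11 and 0.12), venous (0.05 and -0.04), transport (0.12 and -0.02) and neuron lists (-0.06 and 0.29), none past camera.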

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

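Among the tests in this part, both tests of the array scaling, the comparison of the Gata2 change with the range of mast cell genes and the upper limit that Lyve1 sets were chosen only after the result was seen. The change from E14.5 to E18.5 differed between LEC and BEC for 1765 genes by the interaction test of limma, and 56 of the 83 genes named in the report were among them. Splits were drawn that reassigned ages within each cell type after the age change shared by both had been removed. Of 100 such splits, 1, the real one, called as many genes (1765 against at most 9 in the others). The interaction itself stayed in the data and enters the error of the other splits, so their low counts do not exclude chance. With all group means removed, 99 other splits called at most 13 genes. No group difference is left there, so few calls follow from the removal, and these splits do not exclude chance either. With nothing removed, 8 of 99 other splits called as many, up to 9553. There the shared age change can enter the contrast.

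A more positive change in LEC (log2, LEC change minus BEC change) was found for 33 named genes. They were Lyve1 (1.35), Fgl2 (1.35), Reln (2.89), Mrc1 (2.96), Sema3d (2.87), Tc2n (2.17), Scn3a (1.94), Prox1 (2.58), Ptx3 (2.54), Mmrn1 (3.68), F13a1 (4.03), Pard6g (1.74), Dsc3 (2.32), Clec12b (2.74), Ctsj (2.19), Mrgprb1 (5.27), Mrgprb2 (5.08), Mrgprx2 (4.88), Cd163 (4.95), Klrb1f (4.82), Ms4a4a (4.42), Pkhd1l1 (4.67), Tac1 (4.21), Cp (4.23), Esam (1.03), Ccn2 (1.15), Tecrl (1.16), Ankrd1 (1.03), Crmp1 (0.77), Igfbp2 (1.42), Hapln1 (3.23), Rgs18 (2.15) and Gata3 (1.70). Sizes are uncertain for genes that lay below 4.78 at E14.5, such as Mrgprb1, Mrgprb2, Mrgprx2, Cd163, Pkhd1l1 and Tac1. A more positive change in BEC was found for 23. They were Angpt1 (-2.02), Plac8 (-1.57), Mc5r (-0.97), Sele (-2.75), Iigp1 (-2.67), Cxcl10 (-2.21), Il6 (-4.44), Rgs5 (-2.79), Acta2 (-2.38), Car3 (-2.52), Ifi203 (-1.45), Fbln2 (-1.05), C1qtnf9 (-0.99), Agtr1a (-2.23), Nnat (-1.28), Nes (-1.67), Ephx2 (-1.94), Phgdh (-1.60), H4c6 (-0.78), Nkg7 (-1.68), Pdgfrb (-3.73), Galnt15 (-3.04) and Mgll (-2.75). The 14 lists whose changes differed had median differences of 1.53 (lymphatic identity), 0.31 (valve), 0.22 (haematopoietic regulators), -0.32 (Notch), -0.47 (cell cycle), -0.64 (interferon), -0.12 (immediate early), -0.39 (glycolysis), 2.25 (macrophage), 1.66 (mast cell), 0.76 (platelet), 0.81 (keratinocyte), -0.19 (fibroblast) and -1.57 (mural cell).

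The macrophage and mast cell genes were higher in LEC, and mean levels in LEC at E14.5, E16.5 and E18.5 were 12.47, 12.94 and 12.93 for Cpa3, 12.00, 13.20 and 12.71 for Hdc, 9.92, 10.25 and 11.20 for Mrc1 and 6.66, 10.34 and 11.60 for F13a1. The median difference of the 25 genes (2.44) was 2.44 with quantile normalization repeated and 2.39 with the arrays shifted to a common median. Array medians spanned only 5.434 to 5.582, so the shift left between the arrays is too small to account for it. For the same reason neither rescaling could have moved the difference far, and the normalization itself was not tested. RNA of these cells in the LEC isolates is a candidate explanation. Among LEC arrays of 1 age the 16 macrophage genes varied together (mean r 0.55 against 0.00 in random lists, percentile 100), as did the 9 mast cell genes (r 0.71, percentile 100). The random lists were matched on mean level only. Genes expressed together by LEC would vary together as well, so these correlations do not tell the sources apart. Expression by LEC themselves, of Mrc1 and F13a1 for example, stays open and was not tested. None of the 16 macrophage genes is in another list, Kit of the mast cell list is also among the haematopoietic regulators, and the separation of the cells, which might remove such cells, is not given in the sources used here.

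Gata2, which mast cells also express, was higher in LEC (mean levels 10.69, 10.97 and 9.66 against 8.96, 8.64 and 7.74 in BEC). Mast cell RNA in fixed proportion to the mast cell list as the whole source is argued against over the whole interval in LEC, where the change of Gata2 from E14.5 to E18.5 lay below that of the lowest mast cell gene, Kit (-0.03), by -1.0 (SE 0.25). It is not argued against elsewhere: from E16.5 to E18.5 in LEC Gata2 changed by -1.30, Tpsab1 by -1.47 and the median mast cell gene by -0.49, and from E14.5 to E18.5 in BEC Gata2 changed by -1.22 and Cma1 by -1.80. Whether mast cell RNA contributes cannot be told apart from its absence: the deviations of Gata2 and of the mean mast cell gene over the 9 LEC arrays correlated at r = 0.71 (one-sided exact permutation p = 0.056 over 216 permutations), at rho = 0.53 (exact p = 0.12), and at r = 0.35 without the 2 farthest arrays. Higher expression of Gata2 in LEC, RNA of mast cells whose own Gata2 falls with age, and RNA of other Gata2-expressing blood cells stay open, and a split of the signal by cell type would be needed.

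Lymphatic identity genes fell with age in BEC. Their median change (-1.11) was -1.15 with quantile normalization repeated, which makes the ranges equal. The mean interquartile range of BEC arrays was 3.443 at E14.5 and 3.271 at E18.5. The narrower range seen in the values is thus too small to account for the change. For the same reason this rescaling could not have moved the change far, and the normalization itself was not tested. A shift to a common median (-1.11) leaves the range as it is and does not bear on it. RNA of LEC in the BEC isolates of E14.5 cannot be told apart from expression in BEC: 14 of 15 genes implied a positive share of LEC RNA, with a median of 15.7%, a range of 1.3% to 39.9% among the positive ones and an interquartile range of the log2 shares of 1.12. That range met the bound set before the result was seen. The level of Lyve1 in BEC allows at most 5.0% of LEC RNA, less than most genes imply. This limit assumes that LEC in the BEC isolates carry the mean Lyve1 level of the LEC isolates, which was not measured. The other genes allow at most 12.5% (Reln) to 58.2% (Ackr2). A loss of lymphatic transcripts by BEC as they mature therefore stays open beside a share of LEC RNA, whose size these values do not settle.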

How the results depend on the processing

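Of the alternatives, the fit without the E18.5 arrays, which puts E16.5 in their place, was chosen after seeing the data. Prox1 and Gata2 stayed higher in LEC under all 12 other settings and with each array left out (4.11 to 4.24 and 1.90 to 2.08). Leaving out 1 array gave 6898 to 7604 genes for LEC against BEC, 2735 to 2896 at E14.5, 4241 to 4485 at E16.5, 5253 to 6078 at E18.5, 7032 to 8169 for age in LEC, 4928 to 5864 in BEC and 1321 to 1982 for the interaction, and 17 to 19, 16 to 18, 18 to 19, 18 to 20, 10 to 12, 13 to 16 and 10 to 14 lists in the same order. By construction, a minimum difference of 1 lowered the gene counts to 1266, 989, 1538, 1565, 1571, 931 and 666, and an adjusted p under 0.01 lowered the interaction to 923. Fitting only the compared groups gave 4160 genes at E14.5, 5116 at E16.5 and 3707 at E18.5, and array weights 4895, 6125 and 4240, which turns the order of the ages; the cause was not tested. An estimated correlation left 11 lists at E14.5, 9 at E18.5, 0 and 5 for age in LEC and BEC and 5 for the interaction, because it widens the error of lists whose genes vary together, while fry, which does not compare a list with other genes, called 23 for age in LEC. Without the E18.5 arrays, the changes from E14.5 to E16.5 counted 3978 genes in LEC, 3318 in BEC and 839 for the interaction. There 5 values changed sign: Gata3 in LEC against BEC (-0.38), Il3 (0.96), Gata2 (0.28) and Gata3 (-0.06) with age in LEC, and Il6 in the interaction (0.58). None of them was past the test in both this and the main fit. This fit compares other ages than the main one, so these values point to a change after E16.5, whose cause was not tested. The replicate number within each age as a fixed block (9 blocks) gave 7175, 3112, 4830 and 5794 genes for the LEC and BEC comparisons and 1570 for the interaction, and the age changes within a cell type are not estimable with it, since each block lies within 1 age. It was not used as a pairing, since the labels tie no number to a litter and deviations of same-numbered arrays correlated at -0.11 to 0.13. Of the values of single named genes under the alternatives, 2775 kept their side of the threshold, and their direction where they were past it. Another 18 were no longer past it, 10 newly past it and 5 changed sign. Array signal over background limits dim genes: leaving out the dimmer 50% of them gave 5885 genes for LEC against BEC.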

Other observations

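The families in this part and their tests were chosen only after the result was seen, and 8 families were tried. From E14.5 to E18.5, respiratory chain, proteasome, aminoacyl-tRNA synthetase, histone and ribosomal protein genes fell on balance in both cell types. Of 73 respiratory chain genes, 61 fell in LEC (median -0.90, camera adjusted p = 9.1e-23; adjusted p = 0.021 with an estimated correlation) and 54 in BEC (-0.66, adjusted p = 8.8e-21; 0.018), and none rose past the test. Proteasome subunits fell for 33 of 39 in LEC (-0.56, adjusted p = 5.9e-13) and 28 in BEC with 3 rising (-0.52, adjusted p = 1.4e-10), aminoacyl-tRNA synthetases for 25 of 32 in each (-0.59 and -0.44), histone genes for 20 of 31 and 18 with 1 rising in each (-0.75 and -0.61), and cytosolic ribosomal proteins for 42 of 57 with 1 rising and 30 with 2 rising (-0.63 and -0.34, the latter with adjusted p = 0.08 with an estimated correlation). The 317 zinc finger genes named Zfp showed no such change (0.08, adjusted p = 0.31, and 0.02, adjusted p = 0.82).

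Cholesterol synthesis genes fell for 13 of 13 in BEC (median -1.05, camera adjusted p = 4.8e-12; adjusted p = 0.018 with an estimated correlation) and for 7 of 13 in LEC with 1 rising (-0.60, adjusted p = 0.011; adjusted p = 0.25 with an estimated correlation). Over the 3 ages 11 of 13 were higher in LEC (0.62, adjusted p = 4.7e-07; adjusted p = 0.059 with an estimated correlation). The 4 basophil genes Prss34, Mcpt8, Il4 and Cd200r3 were all higher in LEC (median 2.32, adjusted p = 3.4e-06; adjusted p = 0.059 with an estimated correlation), and 3 of them fell in LEC from E16.5 to E18.5 (-1.05, adjusted p = 0.0012; adjusted p = 0.072 with an estimated correlation), the interval in which the mean level of Gata2 fell there. Lymphatic identity genes fell in BEC mainly from E14.5 to E16.5 (11 of 15, -0.78, adjusted p = 2.6e-14; adjusted p = 0.0057 with an estimated correlation), and from E16.5 to E18.5 for 6 of 15 with 2 rising (-0.28, adjusted p = 0.0055; adjusted p = 0.27 with an estimated correlation).

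For LEC against BEC over the 3 ages, 1 of 100 drawn splits that reassigned cell type within ages, the real one, called as many genes (7404 against at most 510). The difference between LEC and BEC enters the error of the other splits and lowers their counts, so chance is not excluded by them. For groups of 3 against 3 the 10 splits are too few for a share under 0.05. There 1 split, the real one, gave as many genes, with the highest other in brackets: 3297 (0) at E14.5, 5032 (0) at E16.5, 6071 (3) at E18.5, 8149 (0) for age in LEC and 6092 (2) for age in BEC.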
